A study of Homo sapiens with 12 samples.

How the data were processed

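Cardiomyocytes were differentiated from the WTC-mEGFP-ACTN2-cl85 line, an established human induced pluripotent stem cell line, and enriched with lactate, per the labels' protocols. They received vehicle, 10 nM endothelin-1, 16 µM sacubitrilat or both for 48 h, with 3 cultures per group. RNA was captured with a poly(dT) primer that carries a unique molecular identifier, and stranded single-end 3′-end-counting libraries were sequenced, per the labels' protocols. Reads were trimmed with fastp 0.24.0 and counted with featureCounts on GRCh38, per the submitters' processing notes. The aligner, the annotation release, the use of the identifiers and the strand setting of the counting are not given in the sources used here, so reads shared between MYH6 and MYH7, between genes and their pseudogenes, and between NPPA and its antisense gene stay uncertain.

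The deposited table holds estimated counts per gene, which need not be whole, and deposited CPM values. The deposited CPM equalled each count as a share of its library total, on the CPM scale (largest difference 1.46e-11), and CPM printed in the text are on that scale. Of 78986 features, 92 were spike-in sequences with 0 counts in every library, and they were left out; 36134 genes had no symbol. Counts were rounded to whole numbers for the tests. Total counts per library were 316932, 80844 and 170644 for vehicle replicates 1 to 3, 1781653, 1473744 and 1719492 for endothelin-1, 1361536, 1268308 and 1953122 for sacubitrilat, and 87281, 158791 and 134950 for both. Intervals and the floor of 3 counts cover counting error only.

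Groups follow the titles, library names and treatment labels. A second line in the description of 6 libraries names a different compound: sacubitrilat for the 3 endothelin-1 libraries and endothelin-1 for the 3 sacubitrilat libraries. If that line were the true one, the endothelin-1 and sacubitrilat groups would change places, and 2228 genes would be called between vehicle and endothelin-1 and 3925 between endothelin-1 and both.

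All 12 libraries entered 1 model with group as the sole term (edgeR 4.0.16 quasi-likelihood test, TMM scaling, filterByExpr, R 4.3.3), which kept 11203 genes, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists (37 lists with 726 distinct genes, 724 matched by symbol and 580 tested) were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members) on log2 CPM computed here from the deposited counts with a prior count of 2, which left 33 lists. The lists, the tests of the 5 planned pairwise comparisons and the interaction, the rule for named genes and all alternatives but the 4 named below as added were fixed before the data were examined. Endothelin-1 against sacubitrilat and the 2 averaged contrasts were added after the library totals were seen. Named genes were a fixed panel (NPPA, NPPB, ACTA1, MYH6, MYH7, MME, EDN1, EDNRA, EDNRB, NPR3 and RCAN1), the 8 largest changes in each direction (4 in the secondary comparisons) among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups, which chance gives for 10% of genes at 3 against 3, and up to 3 called members per list in order of the camera p. Where fewer than 5 genes were called, the rule took the 3 smallest p in each direction.

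The labels give the replicate number as the batch of a library, and the numbers were checked for pairing. Deviations from the group means of same-numbered libraries had r from -0.146 to 0.0396 over 18 pairs, none of them over 0.1. The reported tests have no block, and the value with a block is given where it moves a count by over 1.5 times. The alternatives were RLE scaling, no filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, a replicate block, a fit of the compared groups alone, an estimated correlation in camera, fry, each library left out in turn, mitochondrially encoded genes left out, correlations over genes called in either comparison, and the endothelin-1 and sacubitrilat labels exchanged. Thinning to 80000 counts, leaving out the 2 libraries under 100000 counts, quality weights and the log2 total as a covariate were added later. The filter was applied anew when libraries were thinned or left out. It kept 1855 genes after thinning. Without any 1 endothelin-1 or sacubitrilat library it kept 7228 to 7272, and without any 1 vehicle or combined library 13671 to 14076. The tests were checked on simulated counts in which 200 genes were changed, with 1 spread per gene shared by all groups. For 2-, 4- and 8-fold changes, recovery was 23.8%, 77.4% and 92.2% for vehicle against endothelin-1, and 47.4%, 65.6% and 79.7% for endothelin-1 against both. It was 85.7%, 100% and 100% for endothelin-1 against sacubitrilat, where 11.3% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.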

Results

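The data were 12 libraries of 3′-end mRNA counts from cardiomyocytes differentiated from a human induced pluripotent stem cell line that carries a green fluorescent tag on 1 copy of ACTN2, the gene of sarcomeric alpha-actinin. Each of 4 groups held 3 independently treated cultures. The cells had received vehicle, 10 nM endothelin-1 (a vasoconstrictor peptide that acts through Gq-coupled receptors and enlarges cardiomyocytes), 16 µM sacubitrilat (the active inhibitor of neprilysin, a peptidase that degrades natriuretic peptides and endothelin-1), or both compounds together, for 48 h. The series names vehicle against endothelin-1 and endothelin-1 against endothelin-1 plus sacubitrilat as its primary comparisons. Total counts were unequal between groups. The 6 libraries given a single compound held 1268308 to 1953122 counts, and the 6 vehicle and combined libraries held 80844 to 316932, a 10.1-fold difference of mean totals. A second line in the description of the 6 single-compound libraries names the other compound, and groups here follow the titles, library names and treatment labels. Both primary comparisons therefore set libraries of high total against libraries of low total. Only endothelin-1 against sacubitrilat, and both compounds against vehicle, compared libraries of like total. The summed counts of endothelin-1 were 1.09 times those of sacubitrilat, and those of vehicle 1.49 times those of both. A count of 0 allowed up to 1.54 CPM in the deepest library and up to 37.1 CPM in the shallowest (3 counts per library, counting error only).

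**Figure D1:**
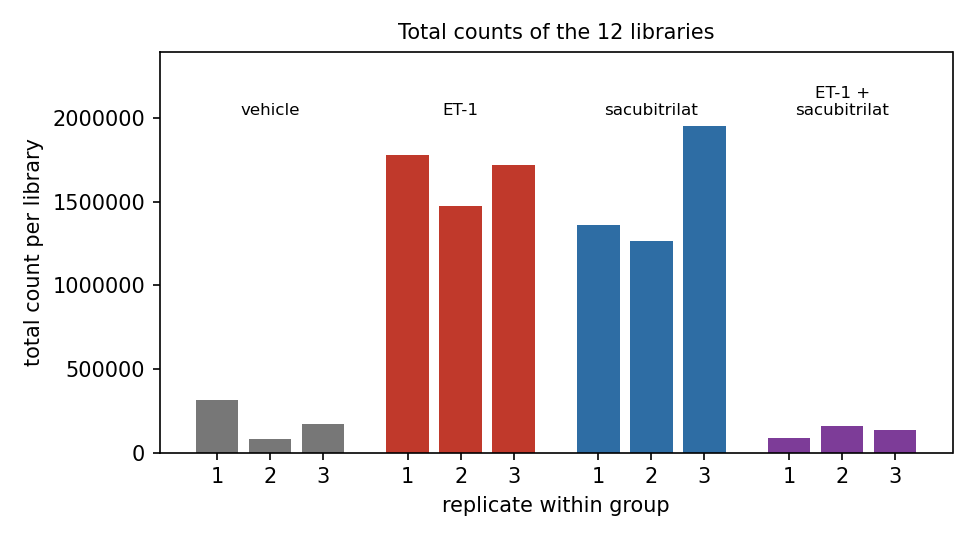
Total counts (linear axis) of each of the 12 libraries, with 1 bar per library and bars grouped by treatment. The endothelin-1 and sacubitrilat libraries lie between 1268308 and 1953122 counts, and the vehicle and combined libraries between 80844 and 316932.

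The hypertrophy panel differed between groups in distinct ways. NPPB (ENSG00000120937, chromosome 1, 11857464 to 11858931 on GRCh38), which encodes brain natriuretic peptide, stood at 75.6 ± 47.9 CPM with vehicle, 559.7 ± 11.03 with endothelin-1, 676 ± 89.9 with sacubitrilat and 45.9 ± 12.6 with both (SD, n = 3 in each group). NPPA (ENSG00000175206, chromosome 1, 11845709 to 11848345), which encodes atrial natriuretic peptide, stood at 560.2 ± 326, 3836 ± 173, 1644 ± 67.6 and 837 ± 289 CPM in the same order. MYH7 (ENSG00000092054, chromosome 14, 23412738 to 23435718), the beta myosin heavy chain of ventricular muscle, stood at 1403 ± 251, 3150.4 ± 153, 1145 ± 105 and 3018 ± 951 CPM, high in both groups that had received endothelin-1. Its neighbour MYH6 (ENSG00000197616, chromosome 14, 23381990 to 23408277), the alpha heavy chain, stood at 791 ± 123, 958 ± 89.4, 1093 ± 41.9 and 754 ± 198 CPM. Reads of these 2 near-identical neighbours are not surely separable. The skeletal actin gene ACTA1 (ENSG00000143632, chromosome 1, 229431245 to 229434098) was at 94.7 ± 51.3, 159 ± 9.97, 257 ± 27.1 and 61.4 ± 50.98 CPM. RCAN1 (ENSG00000159200, chromosome 21, 34513142 to 34615142), a target of calcineurin signalling, was at 24.2 ± 21.5, 82.2 ± 3.66, 60.6 ± 1.89 and 29.7 ± 4.59 CPM. MME, the gene of neprilysin itself, was close to the detection floor (11.2 ± 1.52, 4.07 ± 1.09, 4.64 ± 2.45 and 6.67 ± 6.33 CPM, from 6, 20, 21 and 3 counts), and it was not tested. The receptor genes EDNRB (0, 5, 10 and 1 counts) and NPR3 (2, 32, 25 and 0 counts) were likewise too low to test.

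**Figure D2:**
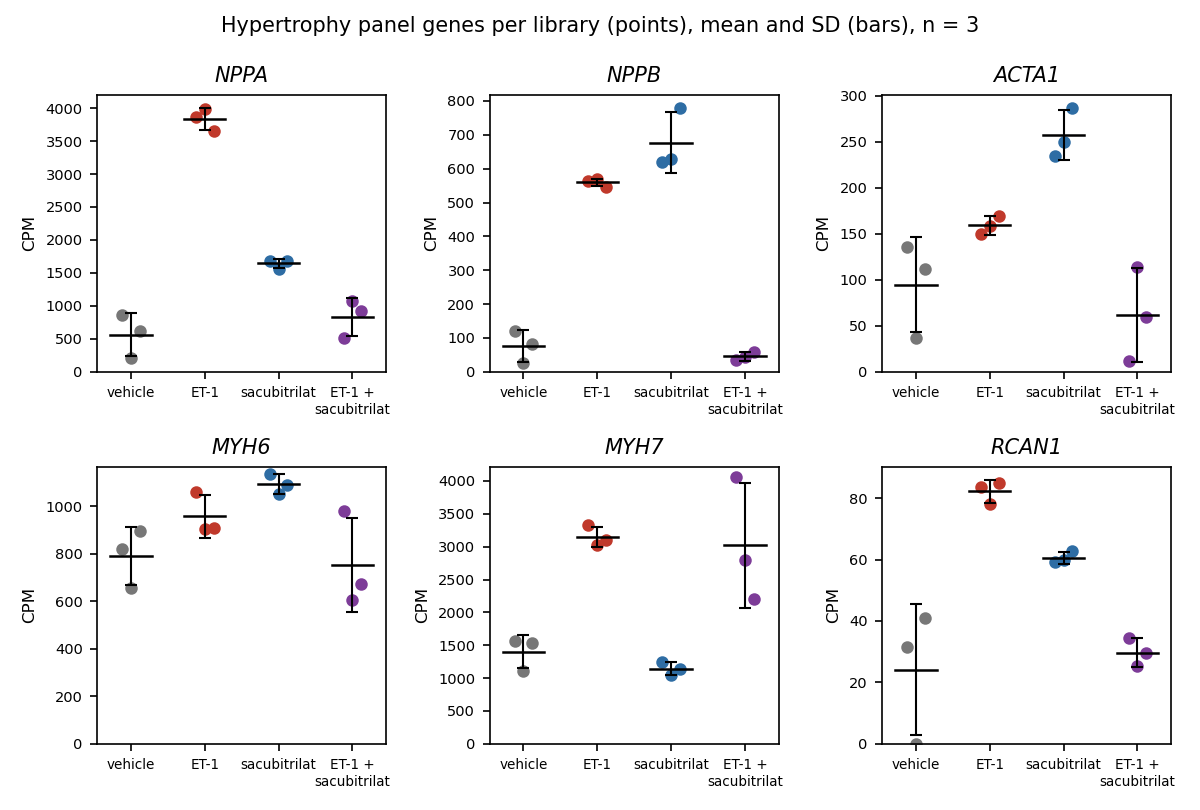
CPM of 6 panel genes (linear axes from 0) in each library (points, 3 per group), with the group mean and SD as bars. NPPB is highest in the endothelin-1 and sacubitrilat groups, whereas MYH7 is highest in the 2 groups that had received endothelin-1.

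Vehicle against endothelin-1 asked which genes the hypertrophic stimulus changed. NPPA, NPPB, 6 of 10 smooth muscle markers and 17 of 27 matrix genes and TGF-beta targets passed as higher with endothelin-1, although no list held with an estimated correlation. NPPA rose by 2.70 ± 0.32 on the log2 scale (6.48-fold, with log2 fold changes given ± SE throughout), NPPB by 2.62 ± 0.25, the smooth muscle actin gene ACTA2 by 2.12 ± 0.23 and MYH7 by 1.22 ± 0.25. These had n = 3 per group and edgeR adjusted p of 3.81e-08, 5.22e-10, 8.46e-09 and 4.72e-04. RCAN1 rose by 1.49 ± 0.33 and the endothelin receptor gene EDNRA by 1.66 ± 0.34. ACTA1 (0.52 ± 0.25, edgeR adjusted p = 0.137) and MYH6 (0.32 ± 0.21, edgeR adjusted p = 0.287) did not pass. EDN1, the gene of endothelin-1, had 2 counts in the vehicle libraries and 120 in the endothelin-1 libraries, a ratio of 6.84 (95% counting interval 1.85 to 57.2).

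Fetal and hypertrophy markers had 14 of 25 higher and 1 lower (16 and 1 adjusted over the list alone), with a median log2 fold change of 1.07. Matrix genes and targets of TGF-beta had 17 of 27 higher and 3 lower (19 and 3 adjusted over the list alone), among them POSTN, the matricellular protein periostin (2.93 ± 0.44), the collagen gene COL5A1 (1.24 ± 0.20) and the fibrillin gene FBN1 (1.48 ± 0.24). Markers of other cell types differed as well, with a median of 0.54 for fibroblast markers and -0.86 for epicardial markers. Targets of p53 had 9 of 19 higher and 0 lower (10 and 0 adjusted over the list alone), led by the cyclin-dependent kinase inhibitor CDKN1A (2.33 ± 0.22). Sarcomere genes had 15 of 30 higher and 2 lower (16 and 2 adjusted over the list alone), ventricular markers 5 of 7 higher and 0 lower (5 and 0 adjusted over the list alone), targets of SRF, MRTF and YAP 9 of 25 higher and 0 lower (11 and 1 adjusted over the list alone), and smooth muscle markers 6 of 10 higher and 0 lower (6 and 0 adjusted over the list alone). Cell cycle genes had 0 of 28 higher and 6 lower (0 and 6 adjusted over the list alone), with the replication helicase subunit MCM4 at -2.58 ± 0.33 and the survivin gene BIRC5 at -1.28 ± 0.32. Amino acid response genes had 1 of 20 higher and 7 lower (1 and 8 adjusted over the list alone). Endoderm and liver markers, a list for another cell lineage, had 0 of 7 higher and 7 lower (0 and 7 adjusted over the list alone), including the epithelial adhesion molecule EPCAM (-2.99 ± 0.34), the apolipoprotein gene APOA2 (-2.79 ± 0.40) and SERPINA1, which encodes alpha-1 antitrypsin (-2.26 ± 0.37). The summed counts of this list were 182 in the vehicle libraries and 333 in the endothelin-1 libraries, a much smaller difference than that of the total counts. The secreted epithelial genes LCN2 (-5.59 ± 0.55) and TFPI2 (-5.24 ± 0.51) also fell, but their spread within vehicle exceeded the mean (235 ± 293 and 325 ± 398 CPM, SD, n = 3). CXCL1, a chemokine gene with 18 and 2 counts, had a ratio of 0.0127 (95% counting interval 0.00143 to 0.0529). CRYAA, which encodes a lens crystallin, had 0 counts with vehicle and 144 with endothelin-1, at least 5.47-fold higher against a floor of 3 counts over the group, and CKMT2, the mitochondrial creatine kinase of muscle, was at least 4.41-fold higher.

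Of 11203 tested genes, edgeR called 2596 between vehicle and endothelin-1, 1231 higher and 1365 lower with endothelin-1 (adjusted p under 0.05). The balance turned with the setting: 1444 higher and 1317 lower with RLE scaling, 1632 and 941 without a filter, 1226 and 1739 with limma-voom. Camera with its preset correlation called 10 of 33 lists, 7 up and 3 down, and with an estimated correlation it called 0, the adjusted p of these 10 lists running from 0.280 to 0.526, while fry called 15. The endothelin-1 libraries held 8.75 times the summed counts of the vehicle libraries. With every library thinned to 80000 counts, an alternative added after seeing the data, 444 of 1855 tested genes and 5 lists were called.

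Endothelin-1 against endothelin-1 plus sacubitrilat asked whether the neprilysin inhibitor altered the endothelin-1 state. Of 1231 genes called higher with endothelin-1 than with vehicle, 900 were called lower with both compounds than with endothelin-1, where independent lists would give 219. The 2 comparisons share the endothelin-1 libraries, and each sets their high totals against low ones, so this overlap alone does not show a reversal by sacubitrilat. NPPB differed by -3.60 ± 0.33 on the log2 scale, NPPA by -2.20 ± 0.31, ACTA2 by -2.51 ± 0.26 and CCN2, the connective tissue growth factor gene, by -4.16 ± 0.35. These had n = 3 per group and edgeR adjusted p of 6.88e-11, 8.53e-07, 1.73e-09 and 1.14e-11. ACTA1 (-1.21 ± 0.34), EDNRA (-2.08 ± 0.44) and RCAN1 (-1.54 ± 0.40) were also lower. For MYH7 the difference of -0.13 ± 0.25 did not pass (edgeR adjusted p = 0.700), nor did that of MYH6 (-0.43 ± 0.22, edgeR adjusted p = 0.126). EDN1 had 120 counts with endothelin-1 and 2 with both, a ratio of 0.218 (95% counting interval 0.0261 to 0.806).

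Fetal and hypertrophy markers had 2 of 25 higher and 17 lower (2 and 17 adjusted over the list alone), with the small heat shock protein CRYAB at -2.33 ± 0.31. Targets of SRF, MRTF and YAP had 2 of 25 higher and 16 lower (2 and 16 adjusted over the list alone), with ANKRD1, a stretch-responsive cardiac repeat protein, at -1.84 ± 0.27 and the smooth muscle calponin CNN1 at -1.91 ± 0.30. Matrix genes and TGF-beta targets had 2 of 27 higher and 21 lower (3 and 21 adjusted over the list alone), with the proteoglycan VCAN at -2.58 ± 0.30 and TGFBI at -2.30 ± 0.33, whereas TGFB1 itself rose by 2.25 ± 0.22. Markers of other cell types moved too: fibroblast markers had 1 of 13 higher and 8 lower (1 and 8 adjusted over the list alone) and a median of -0.94, and smooth muscle markers 0 of 10 higher and 6 lower (0 and 6 adjusted over the list alone) and a median of -1.27. Epicardial markers had 2 of 9 higher and 0 lower (2 and 0 adjusted over the list alone) and a median of 0.92, and camera called none of these 3 lists (adjusted p of 0.105, 0.105 and 0.406). The natriuretic peptide and neprilysin list had 1 of 12 higher and 6 lower (1 and 7 adjusted over the list alone), with GUCY1A1, a subunit of soluble guanylate cyclase, at -2.13 ± 0.29; camera did not call this list (adjusted p = 0.105). Sarcomere genes went both ways, 6 of 30 higher and 12 lower (6 and 12 adjusted over the list alone). CASQ2, the calsequestrin of cardiac calcium stores, had 0 counts with both compounds and 152 with endothelin-1, at least 3.87-fold lower. Endoderm and liver markers had 6 of 7 higher and 0 lower (6 and 0 adjusted over the list alone), with EPCAM at 3.40 ± 0.36, from 55 counts in the endothelin-1 libraries and 46 in the combined libraries. The ribosomal protein pseudogene RPL37P11, with 10 and 22 counts, was higher by 4.72 ± 0.58, and its reads are not surely separable from those of its parent gene.

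In this comparison edgeR called 3854 genes, 1859 higher and 1995 lower with both compounds, where the median over all tested genes was -0.23. The balance depended on the setting: 1537 higher and 3302 lower without a filter, 2315 and 2096 with limma-voom, 2000 and 1709 with DESeq2. Camera called 4 lists, endoderm and liver markers up and fetal and hypertrophy markers, TGF-beta targets and targets of SRF, MRTF and YAP down, and 0 with an estimated correlation (adjusted p = 0.696 for each of them), while fry called 15. The 1859 higher genes took 12.1% to 12.6% of counts in each endothelin-1 library, 32.2% to 40.6% in each combined library and 22.4% to 35.7% in each vehicle library. They were chosen by the difference between the endothelin-1 and combined libraries, so the gap between these libraries follows from the choice. Long noncoding RNA genes took 5.25% ± 0.05 of counts with endothelin-1 and 10.2% ± 0.88 with both (SD, n = 3; 8.58% with vehicle and 5.48% with sacubitrilat), and pseudogenes 1.92% and 3.03%. Mitochondrial ribosomal RNA took 6.03% to 6.06% in each endothelin-1 library and 1.59% to 3.54% in each combined library, against 1.49% to 4.63% with vehicle and 4.14% to 4.77% with sacubitrilat. Thinned to 80000 counts, 792 of 1855 tested genes were called, and without vehicle replicate 2 camera called 7 lists.

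**Figure D3:**
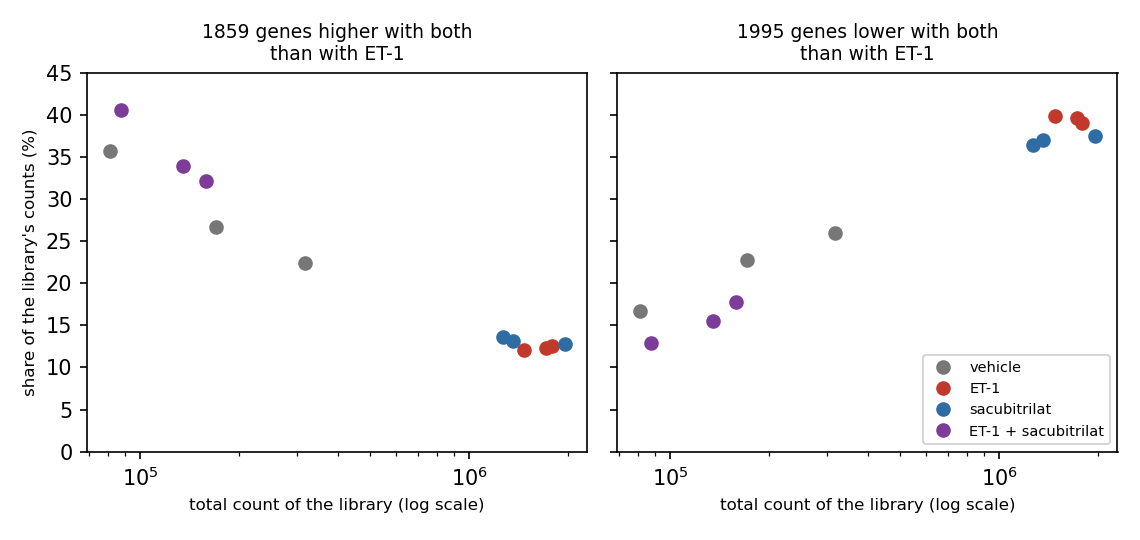
Share of each library's counts (percent, linear axis from 0) held by the genes called higher (left) or lower (right) with both compounds than with endothelin-1, against the library's total count (log axis), 1 point per library. The higher genes took 12.1% to 13.7% of the 6 single-compound libraries and 22.4% to 40.6% of the other 6. The gap between the endothelin-1 and combined libraries follows from how the genes were chosen.

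Sacubitrilat was compared with vehicle in cells without added endothelin-1, across totals that differed 8.06-fold. NPPB rose by 2.78 ± 0.25 on the log2 scale, ACTA1 by 1.10 ± 0.24, NPPA by 1.36 ± 0.31, ACTA2 by 1.05 ± 0.24 and CCN2 by 1.39 ± 0.25. These had n = 3 per group and edgeR adjusted p of 2.30e-10, 9.39e-04, 0.00143, 0.00130 and 7.07e-05. EDNRA rose by 1.61 ± 0.34. MYH7 (-0.36 ± 0.25), MYH6 (0.39 ± 0.21) and RCAN1 (0.93 ± 0.35) did not pass (edgeR adjusted p of 0.329, 0.189 and 0.0565). EDN1 had 2 counts with vehicle and 79 with sacubitrilat, a ratio of 4.89 (95% counting interval 1.31 to 41.1). Fetal and hypertrophy markers had 8 of 25 higher and 1 lower (12 and 1 adjusted over the list alone), p53 targets 5 of 19 higher and 0 lower (6 and 0 adjusted over the list alone) with CDKN1A at 1.18 ± 0.24, and matrix genes and TGF-beta targets 8 of 27 higher and 2 lower (15 and 3 adjusted over the list alone), with TGFB1 at -1.59 ± 0.25; camera called none of these 3 lists (adjusted p of 0.0598, 0.0822 and 0.0598). The median log2 fold change was 0.53 for the matrix list, 0.64 for fibroblast markers and 0.45 for epicardial markers. Endoderm and liver markers had 0 of 7 higher and 6 lower (0 and 7 adjusted over the list alone), the list that camera called (adjusted p = 1.54e-07, and adjusted p = 0.370 with an estimated correlation). TFPI2 (-5.80 ± 0.55) and LCN2 (-5.50 ± 0.55) were lower against the same vehicle libraries, whose spread in these genes exceeded the mean. Of the tested genes, edgeR called 2228, 972 higher and 1256 lower, and 1450 without vehicle replicate 3. With every library thinned to 80000 counts it called 405 of 1855 tested genes. Camera called 0 lists without any 1 endothelin-1 or sacubitrilat library, 4, 2 and 6 without vehicle replicate 1, 2 and 3, and 5, 2 and 2 without combined replicate 1, 2 and 3.

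Both compounds were compared with sacubitrilat alone across totals that differed 12.03-fold. NPPB (-3.76 ± 0.32), ACTA1 (-1.79 ± 0.32), NPPA (-0.86 ± 0.31) and EDNRA (-2.03 ± 0.44) were lower with both, and MYH7 was higher by 1.44 ± 0.25 (n = 3 per group, edgeR adjusted p of 3.01e-11, 3.88e-05, 0.0274, 4.44e-04 and 3.02e-05). The chaperone genes of the unfolded protein response had 0 of 18 higher and 8 lower (0 and 10 adjusted over the list alone), with the calreticulin gene CALR at -1.56 ± 0.23 and the disulfide isomerase PDIA4 at -1.55 ± 0.31; camera did not call this list (adjusted p = 0.0776). Fatty acid oxidation genes had 6 of 22 higher and 2 lower (6 and 2 adjusted over the list alone), with the lipoprotein lipase gene LPL at 2.96 ± 0.59, and camera did not call them either (adjusted p = 0.0935). Fibroblast markers had 1 of 13 higher and 7 lower (1 and 9 adjusted over the list alone), with the proteoglycan DCN at -2.16 ± 0.41 and COL1A1 at -1.15 ± 0.34, and camera did not call them (adjusted p = 0.0935). The phosphoprotein gene ANP32E had 0 counts with both and 212 with sacubitrilat, at least 5.86-fold lower. Endoderm and liver markers had 6 of 7 higher and 0 lower (7 and 0 adjusted over the list alone) and were the 1 list camera called (adjusted p = 3.42e-05, and adjusted p = 0.396 with an estimated correlation). In all, edgeR called 3925 genes, 1929 higher and 1996 lower. Thinned to 80000 counts, 808 of 1855 tested genes and 0 lists were called. Camera called 0 lists without any 1 endothelin-1 or sacubitrilat library, 3, 6 and 3 without vehicle replicate 1, 2 and 3, and 2, 3 and 3 without combined replicate 1, 2 and 3.

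Both compounds against vehicle compared 6 libraries of low total. Vehicle replicate 2 and combined replicate 1 stood apart from their replicates. Chi-square per degree of freedom, a measure of spread against counting error, was 5.31 to 7.94 for replicate pairs that held them. It was 1.95 for the remaining vehicle pair and 2.17 for the remaining combined pair. Few genes passed. The phosphatidylinositol transfer protein gene PITPNM1 rose by 1.65 ± 0.26 on the log2 scale (289 ± 6.81 against 90.6 ± 3.67 CPM, SD, n = 3), the chitinase-domain gene CHID1 by 1.30 ± 0.26, the mitochondrial ribosomal protein gene MRPL30 by 1.29 ± 0.29 and the follistatin-like gene FSTL3 by 1.29 ± 0.29. Lower with both were FTH1, the ferritin heavy chain (-2.05 ± 0.33), the stanniocalcin gene STC2 (-2.65 ± 0.55) and the matricellular YAP target CCN1 (-2.72 ± 0.62). TFPI2 had 120 counts with vehicle (325 ± 398 CPM) and 0 with both, at least 26.8-fold lower, and MLX, a transcription factor gene with 30 and 1 counts, had a ratio of 0.0498 (95% counting interval 0.00122 to 0.299). MYH7 was 1.08 ± 0.26 (edgeR adjusted p = 0.0607), NPPA 0.50 ± 0.33 (0.592), NPPB -0.98 ± 0.49 (0.440) and ACTA1 -0.68 ± 0.43 (0.571), and none of these 4 passed. In total edgeR called 20 genes, 9 higher and 11 lower (1297 at an unadjusted p under 0.05), against 156 with DESeq2, 10 with limma-voom, 10 with the replicate number as a block and 0 when only these 6 libraries were fitted. Camera called 0 of 33 lists (0 with an estimated correlation, 3 with fry). Without vehicle replicate 2, which had the lowest total of all libraries, edgeR called 221 genes, 6 without any 1 endothelin-1 library, 7, 10 and 6 without sacubitrilat replicate 1, 2 and 3, and 7 and 12 without combined replicate 1 and 2; without vehicle replicate 3 camera called 5 lists. On simulated counts of these libraries the test recovered 24.6% of 2-fold, 59.4% of 4-fold and 73.4% of 8-fold changes, so that many 2-fold differences would not have been detectable at this depth. The simulation gave each gene 1 spread in all groups. Chi-square per degree of freedom was 1.95 to 7.94 between vehicle or combined replicates and 1.13 to 1.73 between single-compound replicates. Recovery between vehicle and both may therefore be lower than simulated. The reported tests also gave each gene 1 spread in all groups. The SE and adjusted p printed for vehicle against both may therefore be too small.

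Endothelin-1 against sacubitrilat compared 6 libraries of high total, a comparison added after the totals were seen. With endothelin-1, 6 of 7 ventricular markers and 13 of 30 sarcomere genes passed as higher, and 20 of 28 cell cycle genes and 6 of 9 epicardial markers as lower. The sarcomere list had adjusted p = 0.107 with an estimated correlation. MYL2, the ventricular regulatory light chain, was higher by 2.30 ± 0.16 on the log2 scale (86.4 ± 5.25 against 19.2 ± 1.63 CPM, SD, n = 3), MYH7 by 1.58 ± 0.25, CASQ2 by 3.98 ± 0.33, NPPA by 1.34 ± 0.29 and RCAN1 by 0.56 ± 0.13, with edgeR adjusted p of 3.71e-13, 1.37e-05, 1.73e-11, 0.00101 and 0.00304. ACTA1 differed by -0.58 ± 0.13 and was lower with endothelin-1. NPPB (-0.16 ± 0.15, edgeR adjusted p = 0.587), MYH6 (-0.07 ± 0.19, 0.877), EDN1 (0.60 ± 0.22, 0.0754) and EDNRA (0.05 ± 0.13, 0.876) did not pass. The long noncoding RNA BANCR was higher by 3.52 ± 0.16 and CRYAA, with 144 counts against 1, had a ratio of 133 (95% counting interval 23.4 to 5276).

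Ventricular markers had 6 of 7 higher and 0 lower (6 and 0 adjusted over the list alone), with the LIM-domain gene FHL2 at 1.41 ± 0.13, and sarcomere genes 13 of 30 higher and 1 lower (15 and 1 adjusted over the list alone), with the cardiac troponin I gene TNNI3 at 0.97 ± 0.12. The median was 1.12 for ventricular markers and 0.46 for the 10 tested atrial markers, so the rise was not confined to ventricular genes. Nuclear-encoded oxidative phosphorylation genes had 10 of 41 higher and 0 lower (20 and 0 adjusted over the list alone), with ATP5MC1 at 0.54 ± 0.11 and SDHA at 0.53 ± 0.13. Mitochondrially encoded genes had a median of 0.41. They took 14.08% ± 0.07 of counts with endothelin-1 and 11.34% ± 0.94 with sacubitrilat (SD, n = 3). Glycolysis genes had 10 of 24 higher and 1 lower (11 and 1 adjusted over the list alone), with the muscle enolase ENO3 at 1.56 ± 0.13 and the glucose transporter SLC2A3 at 0.84 ± 0.13. Fatty acid oxidation genes had 4 of 22 higher and 0 lower (4 and 0 adjusted over the list alone) and hypoxia targets 7 of 15 higher and 0 lower (7 and 0 adjusted over the list alone). Cell cycle genes had 0 of 28 higher and 20 lower (0 and 23 adjusted over the list alone), with the topoisomerase TOP2A at -1.23 ± 0.16, the cyclin CCNB2 at -1.44 ± 0.18 and the anaphase activator CDC20 at -1.10 ± 0.14. Epicardial markers, a list for another heart cell type, had 0 of 9 higher and 6 lower (0 and 6 adjusted over the list alone), with the retinoic acid synthesis gene ALDH1A2 at -2.20 ± 0.33; smooth muscle markers had 4 of 10 higher and 0 lower (5 and 0 adjusted over the list alone) and fibroblast markers 1 of 13 higher and 2 lower (1 and 4 adjusted over the list alone).

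Between these 6 libraries edgeR called 1257 genes, 722 higher and 535 lower with endothelin-1. Camera called 20 of 33 lists, and 6 held with an estimated correlation: cell cycle (adjusted p = 6.61e-04), epicardial markers (0.00416), ventricular markers (0.00497), oxidative phosphorylation (0.00497), hypoxia targets (0.0171) and fatty acid oxidation (0.0207). The glycolysis list had adjusted p = 0.0914 with an estimated correlation. The count of genes was 472 with limma-voom, 758 with DESeq2, 2106 when only these libraries were fitted and 681 to 796 without any 1 of them. Thinned to 80000 counts, 9 of 1855 tested genes were called. The direction of this comparison rests on the titles, library names and treatment labels, since a second description line names the other compound.

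**Figure D4:**
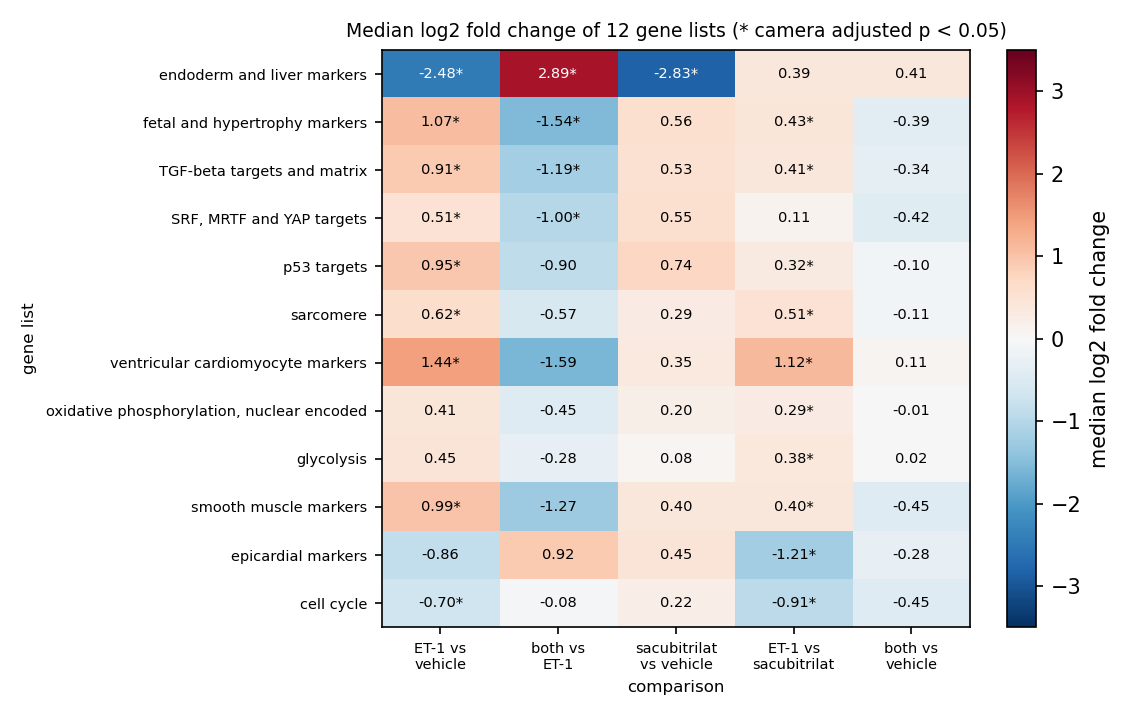
Median log2 fold change of the tested members of 12 gene lists (rows of the heat map) in 5 comparisons (columns), with an asterisk where camera with its preset correlation gave an adjusted p under 0.05. The median of the endoderm and liver markers runs from -2.83 to 2.89 across the 3 drawn comparisons of unequal total and is 0.39 and 0.41 in the 2 comparisons of like total.

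The interaction asked whether the endothelin-1 effect differed with and without sacubitrilat. NPPB had an interaction of -6.38 ± 0.41 on the log2 scale, NPPA -3.56 ± 0.44, CCN2 -5.55 ± 0.44, CDKN1A -4.00 ± 0.36 and FURIN, a protease gene that processes natriuretic peptides, -4.10 ± 0.48. These had n = 3 per group and edgeR adjusted p of 3.34e-15, 2.39e-08, 4.77e-13, 1.62e-11 and 8.44e-09. The interaction of MYH7 was 0.23 ± 0.35 and did not pass (edgeR adjusted p = 0.621). Fetal and hypertrophy markers had 2 of 25 higher and 19 lower (2 and 19 adjusted over the list alone), matrix genes and TGF-beta targets 3 of 27 higher and 21 lower (3 and 21 adjusted over the list alone), targets of SRF, MRTF and YAP 2 of 25 higher and 17 lower (2 and 19 adjusted over the list alone), and endoderm and liver markers 7 of 7 higher and 0 lower (7 and 0 adjusted over the list alone). These 4 lists were called by camera, and 0 with an estimated correlation (adjusted p = 0.645 for endoderm markers and 0.848 for the other 3), while fry called 19. Of 11203 genes edgeR called 5163, 2255 above 0 and 2908 below, and 929 of 1855 tested genes with every library thinned to 80000 counts. The interaction sets the 6 libraries of low total against the 6 of high total.

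Fold changes of the 2 endothelin-1 contrasts, with and without sacubitrilat, shared no library and were opposed across the 11203 genes (Pearson r = -0.626, Spearman rho = -0.661, simulated r of unchanged libraries -0.0541), and genes are not independent replicates. The same held for the 2 sacubitrilat contrasts (r = -0.689, rho = -0.732, simulated r -0.0541). The contrasts of endothelin-1 minus vehicle and of both minus endothelin-1 share the endothelin-1 libraries with opposite sign; their r was -0.710 and their covariance -1.20, against a simulated r of -0.104 and a simulated covariance of -0.0549. Of 2596 genes called between vehicle and endothelin-1, 1966 were also called between endothelin-1 and both, 1963 of them in the opposite direction, where independent lists would give 219 up then down and 226.5 down then up (observed 900 and 1063). Part of this overlap may come from the shared libraries, which are too few to be split. Each pair of contrasts above also set high minus low totals against low minus high totals. A difference that moves with library total would oppose such contrasts. The simulated libraries held no such difference, so the simulated r cannot tell it from an effect of the compounds. The contrasts within libraries of like total, endothelin-1 minus sacubitrilat and both minus vehicle, shared no library and had r = 0.113 (rho = 0.114, simulated r 2.24e-05 with an SD of 0.0163). It was 0.0475 without combined replicate 1 and 0.0549 without the 2 libraries under 100000 counts.

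Averaging each compound over the presence of the other balanced the totals, and these contrasts were also added after the totals were seen. With the labels exchanged as in the second description line, the 2 averaged contrasts would change places. With endothelin-1, MYH7 was higher by 1.33 ± 0.18 on the log2 scale, the angiotensinogen gene AGT by 2.93 ± 0.54, NPPA by 0.92 ± 0.22, the fatty acid binding protein FABP3 by 1.23 ± 0.18 and ENO3 by 1.10 ± 0.13. The tenascin gene TNC (-1.14 ± 0.17), the serine synthesis gene PSAT1 (-1.40 ± 0.27), CDC20 (-1.28 ± 0.27) and the epicardial transcription factor TBX18 (-1.57 ± 0.37) were lower. The average of NPPA joined opposite changes, a rise with endothelin-1 against vehicle and a fall with both compounds against sacubitrilat. Cell cycle genes had 0 of 28 higher and 5 lower (0 and 11 adjusted over the list alone), ventricular markers 2 of 7 higher and 0 lower (2 and 0 adjusted over the list alone) and sarcomere genes 5 of 30 higher and 0 lower (10 and 4 adjusted over the list alone). NPPB (-0.57 ± 0.26) and ACTA1 (-0.63 ± 0.22) did not pass (edgeR adjusted p of 0.273 and 0.136). With endothelin-1 edgeR called 205 genes, 113 higher and 92 lower, and camera 12 lists, of which cell cycle held with an estimated correlation (adjusted p = 0.0200; ventricular markers 0.128, sarcomere 0.492). With the replicate number as a block the count was 121, with DESeq2 369 and with thinning 18. Without vehicle replicate 2 it was 540, and it was 110 to 133 without vehicle replicate 1 or 3, sacubitrilat replicate 3 or combined replicate 1 or 2. Camera called 6 lists without vehicle replicate 2 and 7 without endothelin-1 replicate 3 or sacubitrilat replicate 2. On simulated counts, 2-, 4- and 8-fold changes placed in the endothelin-1 group alone were recovered at 4.76%, 46.8% and 68.8%.

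With sacubitrilat averaged over endothelin-1, few genes passed. On simulated counts, 2-, 4- and 8-fold changes placed in the sacubitrilat group alone were recovered at 15.5%, 49.1% and 68.9%. Of the simulated calls, 10.2% were false. A small count of genes therefore does not show a small effect. The phospholamban gene PLN was at -1.29 ± 0.27 on the log2 scale, the sodium-calcium exchanger SLC8A1 at -1.30 ± 0.29, the Z-disc gene MYOZ2 at -1.42 ± 0.30 and CCN2 at -1.39 ± 0.27. The cell cycle inhibitor CDKN2A (-2.69 ± 0.39), the lysyl oxidase gene LOX (-2.14 ± 0.43), the MHC class I light chain B2M (-0.86 ± 0.19) and the early response gene IER3 (-0.82 ± 0.17) were also lower. The average of CCN2 joined opposite changes, a rise with sacubitrilat against vehicle and a fall with both compounds against endothelin-1. In the panel, NPPA (-0.42 ± 0.22), NPPB (-0.41 ± 0.26) and MYH7 (-0.25 ± 0.18) did not pass (edgeR adjusted p of 0.508, 0.607 and 0.653). Calcium-handling genes had 0 of 23 higher and 3 lower (0 and 7 adjusted over the list alone). In all, edgeR called 29 genes, 6 higher and 23 lower, 16 with the replicate number as a block, 113 with DESeq2, 7 with limma-voom and 0 with every library thinned (1133 at an unadjusted p under 0.05 without thinning). Camera called 4 lists down (hypoxia targets, calcium handling, mitochondrially encoded genes and immediate early genes), and 0 with an estimated correlation (adjusted p from 0.236 to 0.684). The count was 231 without vehicle replicate 2, 46 without vehicle replicate 3 and 9 to 19 without any other single library except combined replicate 1. Camera called 2 lists without vehicle replicate 1, 12 without vehicle replicate 2, 8 and 7 without endothelin-1 replicate 2 and 3, and 8 and 7 without sacubitrilat replicate 1 and 3.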

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

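The 8 results here are tests of the difference between the endothelin-1 contrasts with and without sacubitrilat, a difference that also parts libraries of low total from those of high total. The tests of explanations for the 3 patterns below were chosen after the results were seen, and the expectation for the splits, at a share of 0.05 set beforehand, was written down after their counts were seen. The interaction was called for 5163 genes. Among the panel it was -6.38 on the log2 scale for NPPB, -4.37 for EDN1, -3.69 for EDNRA, -3.56 for NPPA, -2.47 for RCAN1, -2.31 for ACTA1 and -0.82 for MYH6. EDN1 rests on 2 and 2 counts in the vehicle and combined libraries.

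The first pattern is the set of genes that separated the single-compound libraries from the vehicle and combined libraries. Unequal counting depth as the whole cause is argued against by the 929 interaction genes called, of 1855 tested, with every library thinned to 80000 counts. Within vehicle, the genes higher with both than with endothelin-1 took a larger share in replicate 2, the library of lowest total, than in replicate 1 (log2 ratio 0.67, and 0.25 for replicate 3 over replicate 1), and the summed endoderm and liver counts rose with library total with a slope of 0.195, against 0.714 to 1.56 for the other 32 lists. A background that weighs more in libraries of low yield is consistent with both values, and for the endoderm list a like number of counts in every library may account for the call. An interaction of the compounds cannot be told apart from this, since yield moved with the groups and the fold changes of both against endothelin-1 correlated across genes with vehicle replicate 2 minus replicate 1 (r = 0.390 on log2 CPM, simulated 0.0281) and less with replicate 3 minus replicate 1 (r = 0.191, simulated 0.0135). Over the vehicle and combined libraries alone, slopes were 1.89 for smooth muscle markers, 1.74 for fibroblast markers and 1.71 for the natriuretic peptide list. Matrix genes and TGF-beta targets had 1.56. The shares of these lists thus rose with library total there too. Fetal and hypertrophy markers had 1.05, targets of SRF, MRTF and YAP 0.96, and sarcomere genes 0.72.

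The second pattern is the lower NPPB with both compounds than with endothelin-1 (-3.60 on the log2 scale). Dilution of all cardiomyocyte transcripts alike by other counts is argued against by 21 abundant sarcomere genes, whose median was -0.95 (quartiles -1.79 and 0.23). Of these, 5 were called higher and 11 lower, from -3.26 for MYOZ2 to 2.12 for MYL4. ACTC1 (-3.12) and NEBL (-3.10) also fell nearly as far as NPPB, so a steep fall was not particular to NPPB. Loss of the transcript in libraries of low yield stays open: NPPB was lower in vehicle replicate 2 than in vehicle replicate 1 by a log2 ratio of -2.28, but from 2 and 38 counts (ratio 0.206, 95% counting interval 0.0241 to 0.798), and 3 vehicle libraries are too few to decide. NPPA was also lower in vehicle replicate 2 than in replicate 1 (210 against 855 CPM, from 17 and 271 counts). So was ACTA1 (37.1 against 136 CPM, from 3 and 43 counts). MYH7 (1113 against 1559 CPM) and MYH6 (656 against 822 CPM) fell less. An effect of sacubitrilat on the endothelin-1 response, which the design names, also stays open.

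The third pattern is the lower cell cycle transcripts with endothelin-1 than with sacubitrilat (median -0.91). Smooth muscle and epicardial markers had medians that lay 1.61 apart. The smooth muscle list shares ACTA2 with the hypertrophy markers, and ACTA2, TAGLN, CNN1 and ACTG2 with the targets of SRF, MRTF and YAP. Its members may therefore move without a change of cell share, and a lower share of all cells other than cardiomyocytes alike stays open. Fewer cells of an epicardial type alone stays open and was not tested, since 6 of 9 epicardial markers fell with the cell cycle genes (median -1.21). Unequal depth is argued against by sacubitrilat totals on both sides of all endothelin-1 totals, where the endothelin-1 library with most cell cycle CPM still lay below the sacubitrilat library with least (log2 ratio -0.87, largest log2 range within a group 0.07). Exchanged labels stay open, since 6 libraries have label fields that name different compounds, and an exchange would reverse the direction; a difference between the compounds in their effect on proliferation stays open too.

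Each pairwise comparison allows 10 splits of its 6 libraries, too few for a share under 0.05. Parentheses give the number of splits with as many, the real one included, and the highest other. Genes called were 2596 between vehicle and endothelin-1 (1 split with as many, highest other 2), 3854 between endothelin-1 and both (1, highest other 2), 2228 between vehicle and sacubitrilat (1, highest other 0), 3925 between sacubitrilat and both (1, highest other 0), and 1257 between endothelin-1 and sacubitrilat (1, highest other 0). Between vehicle and both, 20 genes were called, 3 splits gave as many, and the highest other gave 92, which points to a structure of the libraries. The 4 splits that placed vehicle replicate 2 with combined replicate 1, the 2 libraries under 100000 counts, gave 92, 65, 9 and 0. Lists called were 10 (1, highest other 8), 4 (1, highest other 2), 1 (9, highest other 2), 1 (1, highest other 0) and 20 (1, highest other 14) in the same order, and 0 between vehicle and both (10, highest other 4).

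For the contrasts of all 12 libraries 100 splits were drawn. The share was under 0.05 for the 5163 interaction genes (1 split with as many, highest other 1743) and for the 205 genes of endothelin-1 averaged over sacubitrilat (3 splits with as many, the 2 others with 252 and 244). For the 205 genes this parts the result only weakly from chance, since 2 other splits called more and leaving out 1 library gave 110 to 540. The share was not under 0.05 for the 4 interaction lists (24, highest other 13), the 12 lists of averaged endothelin-1 (5, highest other 17), the 29 genes of averaged sacubitrilat (6, highest other 244) or its 4 lists (17, highest other 17). Splits that call over 1000 genes point to a structure of the libraries, and the real interaction is the split that parts low from high totals.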

How the results depend on the processing

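Thinning to 80000 counts, the 2 libraries under 100000 counts left out, the log2 total as a covariate, quality weights, and all results of the 3 added comparisons were chosen after seeing the data. Comparisons are listed in the order vehicle against endothelin-1, endothelin-1 against both, vehicle against sacubitrilat, sacubitrilat against both, vehicle against both, interaction, endothelin-1 against sacubitrilat, averaged endothelin-1 and averaged sacubitrilat. Named genes were refitted with RLE scaling, DESeq2, limma-voom, the block, the compared groups alone, each library left out, thinning and the 2 libraries left out, and 0 of their calls reversed there. Calls were lost, however, in 81 of 318 refitted values for vehicle against both. The same held for 78 of 591 for averaged endothelin-1 and 75 of 336 for averaged sacubitrilat. In each other comparison 5 to 16 values lost their call. With the log2 total as a covariate 1 called gene of the interaction was called in the other direction, and exchanged labels would reverse each call between endothelin-1 and sacubitrilat. Of the 2596 genes called between vehicle and endothelin-1, that covariate changed the sign of 591 and left 15 called in the same direction. The cause of a change was not tested unless stated.

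With a mean of at least 50 counts, fewer genes were tested, and 992, 1349, 792, 1351, 51, 1587 and 638 were called in the first 7 and 16 for averaged sacubitrilat. The correlation between endothelin-1 minus sacubitrilat and both minus vehicle was then 0.178, and 0.299 over genes called in either. Thinned, 1855 genes were tested, against 11203 in the main fit. Genes called were then 444, 792, 405, 808, 3, 929, 9, 18 and 0 (for averaged sacubitrilat 29 before thinning, with 1133 at an unadjusted p under 0.05, 113 with DESeq2 and 7 with limma-voom). Lists called when thinned were 5 for vehicle against endothelin-1, 3 for vehicle against sacubitrilat, 0 for sacubitrilat against both, 1 for vehicle against both, 6 for endothelin-1 against sacubitrilat, 3 for averaged endothelin-1 and 2 for averaged sacubitrilat. The correlation of endothelin-1 minus vehicle with both minus endothelin-1 was -0.905. With the log2 total as a covariate, which is nearly aligned with the groups, 27, 28, 22, 31, 42 and 25 genes were called in the first 6.

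Without a filter, 62 genes were called between vehicle and both and 68 for averaged sacubitrilat. With the replicate number as a block, 10 were called between vehicle and both, 121 for averaged endothelin-1 and 16 for averaged sacubitrilat, and no other count moved by over 1.5 times. Fitted alone, the libraries of vehicle and both gave 0 (20 in the joint model, 1297 at an unadjusted p under 0.05, 156 with DESeq2, 10 with limma-voom), and those of endothelin-1 and sacubitrilat 2106. With limma-voom the counts were 10 between vehicle and both, 472 between endothelin-1 and sacubitrilat and 7 for averaged sacubitrilat, and 16 for the last with quality weights. With DESeq2 they were 156, 758, 369 and 113 for vehicle against both, endothelin-1 against sacubitrilat and the averaged contrasts. Without the 2 libraries under 100000 counts they were 126, 1898, 366 and 185 for the same 4. Lists were then 8 for endothelin-1 against both, 2 for vehicle against sacubitrilat, 4 for sacubitrilat against both, 5 for averaged endothelin-1 and 11 for averaged sacubitrilat, and the 4 correlations were -0.433, -0.466, -0.500 and 0.0549.

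With an estimated correlation camera called 0 lists in the first 4 comparisons, the interaction and averaged sacubitrilat, 6 between endothelin-1 and sacubitrilat and 1 for averaged endothelin-1. Fry, which does not compare a list with other genes, called 15, 4, 11, 3, 19, 5, 6 and 2 lists in all but the first comparison. With RLE scaling camera called 2 lists between sacubitrilat and both.

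With each library left out in turn, genes called ranged from 1812 to 2871, 2912 to 4909, 1450 to 2441, 2816 to 5068, 6 to 221, 3718 to 6084, 681 to 1672, 110 to 540 and 9 to 231. The filter kept 7228 to 7272 genes without any 1 single-compound library and 13671 to 14076 without any 1 vehicle or combined library. The ranges thus join the effect of a library with that of the genes tested. Lists ranged from 8 to 15, 3 to 7, 0 to 6, 0 to 6, 0 to 5, 3 to 6, 18 to 20, 6 to 10 and 2 to 12. The correlations ranged from -0.754 to -0.433, -0.813 to -0.478, -0.840 to -0.507 and 0.0475 to 0.136. The extremes came without vehicle replicate 2 for 221, 540 and 231 genes and without vehicle replicate 3 for 1812 and 1450.

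Panel values that changed sign had not been called. Thinned, MYH7 was 0.128 between endothelin-1 and both and MYH6 0.0566 for averaged sacubitrilat. With the block, MYH6 was 0.0042 and EDN1 0.0505 for averaged sacubitrilat. With limma-voom, RCAN1 was 0.377 between vehicle and both, EDNRA 0.0184 for averaged endothelin-1 and EDN1 0.0504 for averaged sacubitrilat. Without the 2 libraries under 100000 counts EDN1 was -0.323 between vehicle and both. With each library left out in turn, averaged sacubitrilat gave ACTA1 from -0.525 to 0.164, EDN1 from -0.335 to 2.26 and MYH6 from -0.157 to 0.0452, and averaged endothelin-1 gave EDNRA from -0.425 to 0.0401. Vehicle against both gave EDN1 from -0.0651 to 5.12, EDNRA from -0.908 to 0.0319 and RCAN1 from -0.426 to 0.104. EDNRA ranged from -0.0222 to 0.159 between endothelin-1 and sacubitrilat. MYH7 ranged from -0.433 to 0.0358 between endothelin-1 and both, and its interaction ranged from -0.360 to 0.493. Depth limits the comparisons with the vehicle and combined libraries, where the floor reached 37.1 CPM in the shallowest library.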

Other observations

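Between endothelin-1 and sacubitrilat, further genes with steep changes were these. The water channel gene AQP3 (-2.41 ± 0.28 on the log2 scale), the nephrin gene NPHS1 (-2.52 ± 0.48), the homeobox gene LHX1 (-2.40 ± 0.33) and the integrin gene ITGB8 (-2.36 ± 0.28) were lower with endothelin-1 (n = 3 per group, edgeR adjusted p of 3.86e-08, 2.74e-04, 1.35e-06 and 6.44e-08). Muscle genes higher with endothelin-1 included the M-band gene MYOM2 (2.31 ± 0.38), the myosin gene MYH7B (1.56 ± 0.19) and SLN, the sarcolipin gene of atrial calcium uptake (2.34 ± 0.34). The protease inhibitor gene A2M was higher by 2.86 ± 0.25.

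Of 6656 genes with a mean of at least 20 counts, 30 had counts that barely rose with the library total (slope under 0.25, median slope 1.10). Among them, chosen after their values were seen, was PIGR, the epithelial immunoglobulin receptor, with 22 to 53 counts in every library. With genes at 0 set to their bound, the sarcomere median between vehicle and sacubitrilat moved from 0.29 to 0.13 and the epicardial median between vehicle and both from -0.28 to 0.09.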
